A study of Mus musculus with 46 samples.

How the data were processed

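RNA of the nucleus accumbens, a forebrain region of reward and motivation, was measured on 46 Affymetrix MTA 1.0 arrays, 1 per male mouse. The mice belonged to the inbred strains C57BL/6J and DBA/2J. Each carried an osmotic minipump with nicotine (24 mg per kg per day) or saline for 14 days. The chronic groups kept the pump until death, and the withdrawal groups had it taken out 24 h before. Per the labels, mice were kept 4 to a cage and every RNA integrity number exceeded 8. No batch, date or cage number is given in the sources used here, so no batch could be tested.

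The table the authors deposited holds 1 value per array and transcript cluster in log2 units, from 2.58 to 19.9, already scaled between arrays, with array medians from 6.52 to 6.63. The summarisation and scaling methods, the probe filter and the genome build are not given in the sources used here. That table has 48088 features, of which 6732 are control features. Only 13 of its features lie on chromosomes 1 to 6 by their identifiers, and the first part of chromosome 7 is missing too. Apart from those few features, per-array values of these regions could not be analysed here. The second table the authors deposited holds, per the file headers, an S-score for each of 22 nicotine mice against all saline mice of its strain and phase. The score values, as deposited, are signed and standardised differences that the authors computed from the arrays, in score units and not as fold changes, and the software and method are not given in the sources used here. This table covers all chromosomes (26272 features, 25802 genes) and supplied the gene names and coordinates. Of its genes, 9234 lie on chromosomes 1 to 6 and 9548 have no per-array values. The coordinates overlapped the gene of the same name in the mouse GRCm38.p6 annotation for 98.9% of 23561 genes compared. All sample columns were mapped, and 22 of 22 nicotine mice had log2 differences that correlated best with their own S-score column (r from 0.593 to 0.854).

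Features with exactly 1 gene symbol were kept, 1 per gene, that with the highest mean. Genes had to exceed the 50th percentile of the non-control features of the same array on at least 5 arrays. This left 9596 of 16254 genes and removed 6658. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per group, 38 residual and 4.14 prior degrees of freedom, two-sided), with data.table (version 1.17.8) and jsonlite (version 2.0.0) for input and output and matplotlib 3.10.9 in Python 3.11.15 for the plots. There were 13 contrasts. They were nicotine against saline in each strain and phase, the mean over the strains in each phase, the strain and phase differences of the nicotine effect, pump removal among saline mice of each strain, and DBA/2J against C57BL/6J among saline mice. P-values were adjusted by Benjamini-Hochberg within each contrast with a threshold of 0.05. The S-scores were tested per gene in 2 ways. In the first, with limma, the saline mice were assumed to vary like the nicotine mice and their number entered the error. In the second the scores were tested against 0 without the spread of the saline mice. The second way treats the shared saline reference as free of error: on simulated data without any effect it gave unadjusted p-values under 0.05 for 14.7% to 16.5% of genes, where limma gave about 5%.

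Gene lists, 45 in all with 870 entries, were fixed for the tissue and the treatment. Of the entries 792 were found in the comparison table, and 41 lists had at least 3 tested genes (44 by S-score). Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation, fry and an exact permutation of the mean list value per mouse stood beside it. The genes to name were also set by rule. Of genes at adjusted p under 0.05, the 10 with the largest rise and the 10 with the largest fall were named. Where fewer than 20 genes passed, those with the smallest p were added, up to 10 in each direction, as values that did not pass. Up to 4 members with the smallest p were named of each list that passed camera. A fixed set of 16 genes was summarised in each nicotine contrast, and strain check genes were read in the strain contrast. Predicted genes were counted, and named only where fewer than 10 others remained. The groups, the contrasts, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were other filters, scalings, fits, set tests, covariates for tissue composition, the authors' S-scores, mouse number as a block and each mouse left out in turn. Testing S-scores against 0, the exact list permutation and cyclic loess were added after the data were seen.

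In simulated data with 200 changed genes and the spread of these arrays, changes of 1.41-fold were recovered in 88.2% to 92.8% of genes and 2-fold changes in 99% or more. Changes of 1.19-fold were recovered in 42.8% to 53.8%. The simulated noise was independent between genes, and the 200 genes held sizes from 1.19-fold to 4-fold. Recovery may therefore be lower for a response of few or only small changes. The number of arrays limits the precision, and the median standard error of a nicotine contrast was 0.07 on the log2 scale.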

Results

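The transcriptome of the nucleus accumbens was measured in 46 male mice of 2 inbred strains, C57BL/6J and DBA/2J, to ask how long nicotine delivery by a minipump and a day without it change gene expression. The chronic groups held 5 nicotine and 6 saline mice of C57BL/6J and 6 nicotine and 6 saline mice of DBA/2J. The withdrawal groups held 6 nicotine and 6 saline mice of C57BL/6J and 5 nicotine and 6 saline mice of DBA/2J. Each mouse had 1 array, and every array correlated with the mean of the others of its group at 0.993 or higher. The spread of an array's genes around the group mean was 0.14 (log2, median over arrays), with 0.12 and 0.22 as the extremes. The component that took most of this spread (15.0%) separated mice by markers of neighbouring tissue. Cortical excitatory neuron genes lay at one end, and olfactory tubercle and striatal dopamine genes at the other. Per-array values cover chromosomes 8 to 19, X and Y, the mitochondrion and most of chromosome 7. Nearly all genes of chromosomes 1 to 6 entered through the authors' S-scores alone, since only 13 per-array features lie there by their identifiers. Nicotine differences below are nicotine minus saline on the log2 scale.

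Chronic nicotine in C57BL/6J was asked about first. Genes that respond to glucocorticoids, the adrenal stress hormones, were lower in nicotine mice as a group by -0.18 (camera adjusted p = 4.5e-04, and adjusted p = 0.591 with an estimated correlation). Without C57BL/6J chronic saline mouse 1, which stood highest at 0.49, the difference was -0.11 and the adjusted p was 0.109. Their mean was -0.01 ± 0.13 (SD, n = 5) under nicotine and 0.17 ± 0.18 (n = 6) under saline, and 14 of 14 tested members had lower values. Among them were Tsc22d3, a leucine zipper protein induced by glucocorticoids (-0.19), the Krüppel-like factor Klf9 (-0.24), the NF-kappa-B inhibitor Nfkbia (-0.21) and the sulfotransferase Sult1a1 (-0.43). Genes of oxidative phosphorylation, the chain of mitochondrial complexes that makes ATP, were lower too in 29 of 31 members, by -0.11 on average (adjusted p = 1.5e-05, and adjusted p = 0.685 with an estimated correlation). Atp5d stood at -0.21, Atp5o at -0.15, Cox5a at -0.24 and Ndufs7 at -0.14. The 6 tested markers of meninges and fibroblasts were higher by 0.28 on average (adjusted p = 0.00231, and adjusted p = 0.685 with an estimated correlation). That value was 0.14 without nicotine mouse 4, where the adjusted p was 0.0790, and 0.42 without nicotine mouse 2 or saline mouse 5.

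In the glucocorticoid list 5 of 5 nicotine mice lay under the saline mean, as they did in oxidative phosphorylation, which passed in 11 of 11 repeats that each left out 1 mouse. For meninges and fibroblasts 4 of 5 mice lay above it. The 5 tested genes of inflammation and the acute phase, among them Cebpd (-0.22), C4b (-0.16), Osmr (-0.18) and Serpina3n (-0.34), were lower by -0.19 on average with adjusted p = 0.0189 and 5 of 5 mice under the saline mean. Their adjusted p = 0.591 with an estimated correlation, and it was 0.228 without saline mouse 1 (where the mean difference was -0.10), 0.109 without saline mouse 3, 0.0502 without nicotine mouse 2 and 0.0567 without nicotine mouse 4. Oligodendrocyte precursor markers, such as the receptor Gpr17 (0.17) and the proteoglycan Cspg4 (0.07), were higher in 6 of 9 members by 0.05 on average, with adjusted p = 0.0353 and 4 of 5 mice above the saline mean. That call gave adjusted p = 0.591 with an estimated correlation, and it was lost without any 1 of nicotine mice 1 (0.223) and 2 (0.121) and saline mice 1 (0.109), 2 (0.122), 5 (0.125) and 6 (0.181). The precursor value was 0.03 without nicotine mouse 2 or saline mouse 2, 0.02 without saline mouse 6 and 0.09 without saline mouse 4. Among genes above the 75th percentile the glucocorticoid call was lost (0.104), as was that of the precursors (0.614), and meninges and inflammation had fewer than 3 genes. With no filter inflammation (0.214) and the precursors (0.220) were lost. The precursor call also went with all features (0.357), median-centred arrays (0.105), quantile normalization (0.121), cyclic loess (0.105) or only these groups fitted (0.0524). In the authors' S-scores, which add chromosomes 1 to 6, the glucocorticoid list passed camera with a preset correlation (adjusted p = 2.5e-11) and with an estimated one (adjusted p = 0.0246). These scores come from the same arrays and use the same saline mice as reference, saline mouse 1 among them. That mouse could not be left out of the scores, so they are not separate evidence.

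No single gene passed in chronic C57BL/6J mice. With limma, 0 of 9596 genes had an adjusted p under 0.05 (lowest 0.992), and 449 had an unadjusted p under 0.05, where 479.8 would by chance. Of these 449, 396 were lower, but the median of all genes differed by -0.03 too, and with arrays centred on their median 146 of 332 were lower. The S-scores gave 0 of 25802 genes (808 unadjusted) with the spread of the saline mice, and 5 against 0. Those 5, named after their values were seen, were the iron-binding lipocalin Lcn2 (mean score -4.60), Igfbp7 (-2.90), Ly6a (-2.56), Ccsap (-1.82) and the retinoid isomerase Rpe65 (4.49). On simulated data without an effect the test against 0 called 109 of 9596 genes on average in this contrast, so the 5 calls are no evidence of a change. Saline mouse 1 is part of the reference of these scores. Genes with the smallest p, as values that did not pass, included BC031181 at -0.32 (SE 0.08) and Ndn, an imprinted gene of neurons, at -0.36 (SE 0.10), each lower in 5 of 5 mice with a limma adjusted p of 0.992. Lower values were also seen for the leukocyte integrin Itgb2 (-0.16), Trpt1 (-0.23), Dele1 (-0.17), Tmem267 (-0.50), Tmed10 (-0.20), the small GTPase Rhob (-0.33), Saraf (-0.29) and Chrac1 (-0.25). Higher values were seen for the spectrin Sptbn1 (0.19), Defa39 (0.45), Misp (0.17), Lrrc2 (0.22), the astrocyte water channel Aqp4 (0.30), Ighv9-4 (0.53), Ffar1 (0.29), Ephb3 (0.14), Fhit (0.16) and Col6a2 (0.15). Of the 16 genes set in advance for the nicotinic, dopamine and opioid systems and neuronal activity, 10 had array values and 7 passed the intensity filter. None of the 7 passed, 0 had an unadjusted p under 0.05, and they ran from Fos (-0.21) to Chrna7 (0.04), which was -0.01 without saline mouse 1. By S-score 0 of the 16 passed and 0 had an unadjusted p under 0.05. The 95% interval of 97.2% of genes lay within 0.5 of 0, a 1.41-fold change.

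In DBA/2J mice on chronic nicotine, genes of the myelin-forming oligodendrocytes were lower as a group (camera adjusted p = 5.9e-08, and adjusted p = 0.608 with an estimated correlation). Their mean was -0.26 ± 0.16 (n = 6) against -0.07 ± 0.12 (n = 6) under saline, and 14 of 14 members had lower values. The iron carrier Trf stood at -0.40, and the myelin genes Mobp and Mog at -0.36 and -0.28. Immediate early genes, which neurons switch on when active, were lower in 15 of 17 members by -0.25 on average (adjusted p = 3.1e-05, and adjusted p = 0.608 with an estimated correlation). Without nicotine mouse 1, which stood at -0.73, the value was -0.15. The nuclear receptor Nr4a1 stood at -1.0, Dusp6 at -0.39, Fos at -0.48 and Egr1 at -0.35. Genes of striatal dopamine signalling were higher in 14 of 15 members by 0.19 on average (adjusted p = 0.00416, and adjusted p = 0.676 with an estimated correlation). These included the dopamine receptors Drd2 (0.37) and Drd3 (0.46), the G protein Rasd2 (0.25) and the phosphatase Ptpn5 (0.23). Markers of cortical excitatory neurons, cells that lie outside the accumbens, were lower in 9 of 12 members by -0.23 on average (adjusted p = 0.00416, and adjusted p = 0.676 with an estimated correlation). That value was -0.14 without nicotine mouse 1, where the adjusted p was 0.0662, and -0.15 without mouse 2 (0.0682). Nrn1 stood at -0.80, Hs3st2 at -0.47, the glutamate transporter Slc17a7 at -0.61 and Sv2b at -0.41.

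In the oligodendrocyte, immediate early and cortical lists 5 of 6 nicotine mice lay under the saline mean, and in the striatal list 5 of 6 above it. The first 2 passed camera in 12 of 12 repeats without 1 mouse. Striatal dopamine signalling was lost without DBA/2J chronic saline mouse 3 (0.109) or nicotine mouse 6 (0.0737). The cortical call was lost with no filter (0.0588), all features (0.0578) or median-centred arrays (0.0639). With 3 composition covariates, 2 of which are the means of the oligodendrocyte and cortical lists, those 2 lists (0.517, 0.548) and the striatal one (0.592) did not pass, and immediate early genes did. Adjusted over the list alone, 2 genes of the opioid system, 1 of neurotrophin signalling and 1 of ependymal cilia passed, where 0 did over all genes tested. The two-sided exact permutation of list means passed 2 lists with 3 and 4 tested genes, ependymal cilia (-0.08) and neurotrophin signalling (0.10), each with adjusted p = 0.0444, and camera passed neither (adjusted p = 0.169 for each). For the oligodendrocyte list its unadjusted p was 0.0411.

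Single genes did not pass in chronic DBA/2J mice either: limma called 0 of 9596 (lowest adjusted p = 0.607), with 768 at an unadjusted p under 0.05 (585 higher, 183 lower). The median of all genes differed by 0.02, and with arrays centred on their median 187 were higher and 485 lower. The S-scores called 0 with the spread of the saline mice (1458 unadjusted) and 113 against 0. The smallest p belonged to Rcan1, a regulator of the phosphatase calcineurin (chromosome 16, 92391951 to 92466169), at 0.27 (SE 0.07, limma adjusted p = 0.607), higher than the saline mean in 6 of 6 mice. Other higher values, none past the threshold, were Cpsf6 (0.22), Zfp827 (0.21), the histone gene H2bc8 (0.45), Qpctl (0.26), Letmd1 (0.19), Nudt16l1 (0.25), Hmgb2 (0.27), the protocadherin Pcdh8 (0.32) and Ttc5 (0.17). Lower ones were Serpinb6b (-0.26), Fam50b (-0.31), Acyp1 (-0.23), Hmgb1-ps6 (-0.26), Mapk12 (-0.21), Gucy2g (-0.25), Afap1l1 (-0.15), Nkd1 (-0.16) and Cdc42ep4 (-0.15). Of the fixed genes 0 of 7 passed, 2 had an unadjusted p under 0.05 (Drd2 at 0.37 and the nicotinic receptor gene Chrna7 at 0.17), and the lowest was Arc at -0.52. By S-score 0 of 16 passed and 4 had an unadjusted p under 0.05. The interval of 96.4% of genes lay within 0.5 of 0.

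**Figure D1:**
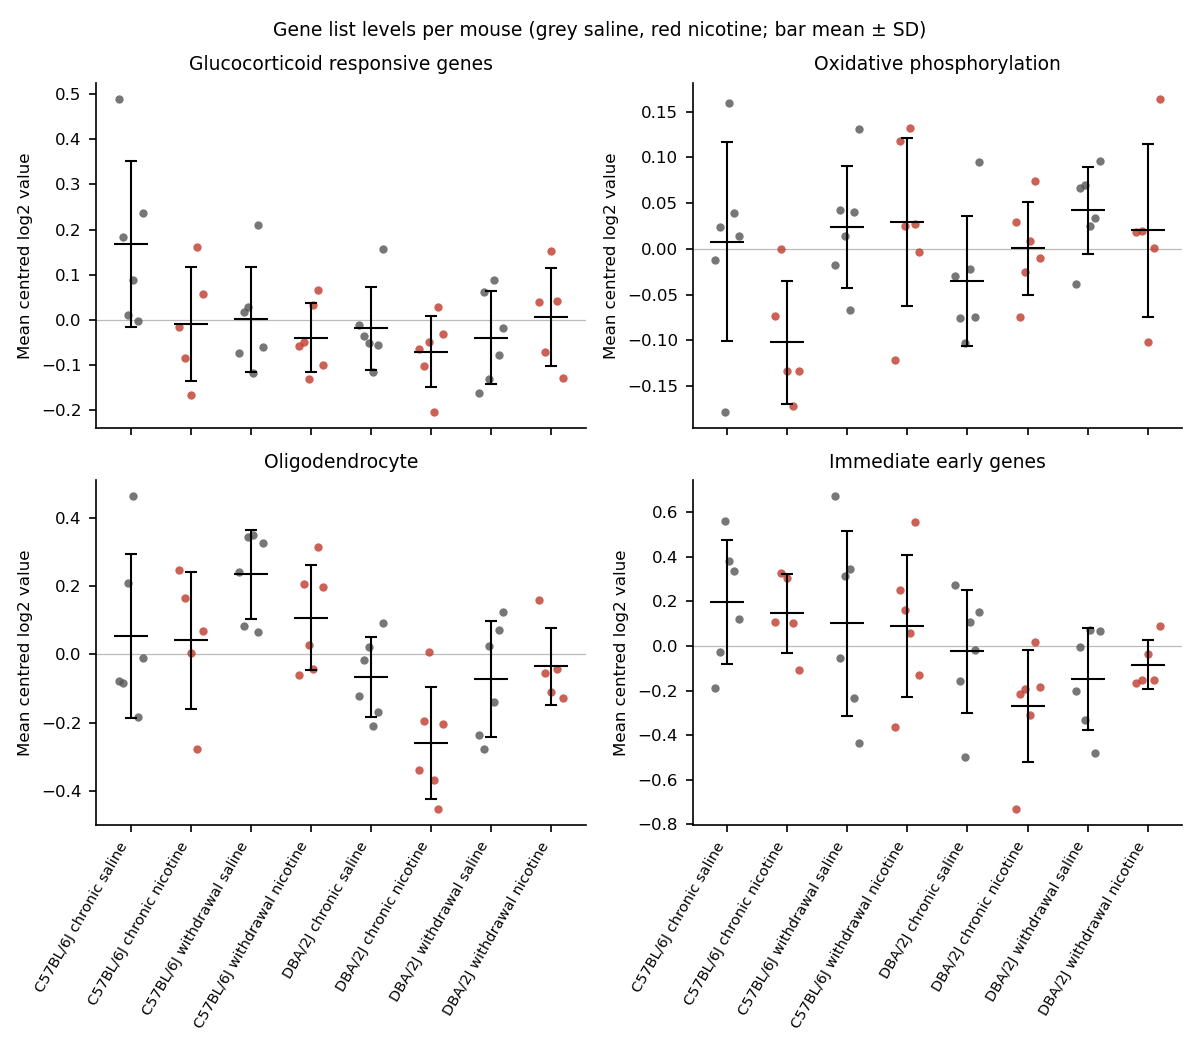
Mean centred log2 value per mouse of 4 gene lists (glucocorticoid responsive, oxidative phosphorylation, oligodendrocyte, immediate early) in the 8 groups, with saline mice in grey, nicotine mice in red, and bars for the mean ± SD of 5 or 6 mice. Glucocorticoid responsive genes averaged 0.17 in C57BL/6J chronic saline mice and -0.01 in their nicotine mice, and the mice of every group spread widely around their mean.

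The strains were then compared in their response to chronic nicotine. The oligodendrocyte list differed by -0.18 (DBA/2J minus C57BL/6J response, 14 of 14 members negative, adjusted p = 0.783 with an estimated correlation), and oxidative phosphorylation by 0.15 (29 of 31 positive, adjusted p = 0.860 with an estimated correlation). The median of all genes differed by 0.06, which raises the oxidative phosphorylation value and its count of positive members. Immediate early genes differed by -0.20 and cortical excitatory neurons by -0.25 (each adjusted p = 0.860 with an estimated correlation), and meninges and fibroblasts by -0.45 (adjusted p = 0.783 with an estimated correlation). By camera the adjusted p was 5.2e-05 for oligodendrocytes and 0.00575 for each of the other 4 lists. Of these, only the oligodendrocyte call passed in 23 of 23 repeats without 1 mouse. The oligodendrocyte call passed under the filters, scalings and weights tried, but not with composition covariates (0.400), which hold that list's own mean. Immediate early genes were lost with no filter (0.191), all features (0.244), median-centred arrays (0.134), quantile normalization (0.104), cyclic loess (0.0959) or covariates (0.0505). Oxidative phosphorylation was lost above the 75th percentile (0.0652), with quantile normalization (0.0922) or with cyclic loess (0.0695). Meninges and fibroblasts were lost with median-centred arrays (0.101), quantile normalization (0.0895) or cyclic loess (0.0816), and had fewer than 3 genes above the 75th percentile. Cortical neurons were lost with no filter (0.153), all features (0.153), median-centred arrays (0.134), quantile normalization (0.0552), cyclic loess (0.0695) or covariates (0.497). Leaving out a mouse, immediate early genes were lost without C57BL/6J saline mouse 1 (0.0659, value -0.12), DBA/2J nicotine mouse 1 (0.0945, value -0.10) or DBA/2J saline mouse 1 (0.0814). Oxidative phosphorylation was lost without C57BL/6J nicotine mouse 4 (0.0514), C57BL/6J saline mouse 4 (0.0670) or DBA/2J saline mouse 1 (0.0541). Meninges and fibroblasts were lost without DBA/2J nicotine mouse 4 (0.0639, value -0.28), and cortical neurons without C57BL/6J saline mouse 6 (0.0747, value -0.14) or DBA/2J nicotine mouse 1 (0.0539, value -0.16). With limma 0 of 9596 genes differed (lowest adjusted p = 0.194), with 955 at an unadjusted p under 0.05 (819 higher, 136 lower). With arrays centred on their median 196 were higher and 539 lower. The S-scores gave 0 (1757 unadjusted), or 16 against 0. Nearest to passing were Ndn (0.63), Rcan1 (0.42) and the glutaminyl cyclase Qpctl (0.46), each with adjusted p = 0.194. Higher responses in DBA/2J that did not pass also came from BC031181 (0.46), Nudt16l1 (0.43), Alg10b (0.32), Nop9 (0.27), Mis18a (0.33) and the histone genes H2bc8 (0.72) and H3c6 (0.73), and lower ones from Misp (-0.26), Nkd1 (-0.26), Col12a1 (-0.47), Prss53 (-0.26) and Serpinb6b (-0.31). Without C57BL/6J chronic saline mouse 3, 5 genes passed: Nudt16l1 (0.51), H3c6 (0.87), Ndn (0.68), Stim1 (0.32) and Nop9 (0.32), named after their values were seen. Of all arrays that mouse had the largest spread around its group mean (0.22) and the lowest correlation with the rest of its group (0.993). Its cortical neuron list stood at 0.51 and its striatal dopamine list at -0.46.

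Averaged over the strains, glucocorticoid responsive genes were lower under chronic nicotine in 13 of 14 members, by -0.11 on average (camera adjusted p = 4.9e-06, and adjusted p = 0.192 with an estimated correlation). Tsc22d3 stood at -0.13, Klf9 at -0.16 and Plin4 at -0.20. The exact permutation of list means, with 426888 splits, passed 0 lists in this average (lowest adjusted p = 0.802). By camera the glucocorticoid list passed in 23 of 23 repeats without 1 mouse. In the S-scores, which rest on the same arrays and saline mice, the list passed camera with an estimated correlation too (adjusted p = 0.0194). Immediate early genes (-0.15, adjusted p = 0.00105), oligodendrocyte genes (-0.10, adjusted p = 3.7e-04) and oxidative phosphorylation (-0.04, adjusted p = 0.00599) were lower, and striatal dopamine signalling was higher (0.08, adjusted p = 0.00172). For these 4 lists the adjusted p = 0.612 with an estimated correlation. The averages do not show a shared direction in every list. Oxidative phosphorylation was -0.11 in C57BL/6J but 0.04 in DBA/2J (0.02 to 0.06 with 1 mouse left out). In C57BL/6J, leaving out 1 mouse changed the sign of striatal dopamine signalling (-0.12 to 0.03), immediate early genes (-0.13 to 0.02) and oligodendrocyte genes (-0.06 to 0.07), while DBA/2J had 0.19, -0.25 (-0.15 without nicotine mouse 1) and -0.19. Glucocorticoid responsive genes stood at -0.18 in C57BL/6J (-0.11 without saline mouse 1) and at -0.05 in DBA/2J (-0.07 to -0.02). Glutamate receptors were higher (0.05, adjusted p = 0.00789), with Grm5 at 0.14, Gria1 at 0.13 and Grik2 at 0.18, and inflammation was lower (-0.10, adjusted p = 0.00522). For this pair the adjusted p = 0.192 with an estimated correlation. Glutamate receptors had 0.10 in DBA/2J and -0.02 to 0.03 in C57BL/6J with 1 mouse left out, and inflammation -0.19 in C57BL/6J (-0.10 without saline mouse 1) and -0.05 to 0.02 in DBA/2J. Of inflammation genes, 1 passed adjusted over the list alone and 0 over all genes tested. Without C57BL/6J saline mouse 3 the striatal (0.215, value 0.03) and immediate early (0.0710) calls were lost, and without saline mouse 1 that of inflammation (0.0602, value -0.06). The oligodendrocyte call was lost without C57BL/6J nicotine mouse 4 (0.0583), and its value was -0.06 without that mouse or saline mouse 4. Oxidative phosphorylation was lost without C57BL/6J nicotine mouse 4 (0.0634), C57BL/6J saline mouse 4 (0.0866, value -0.02) or DBA/2J saline mouse 6 (0.0786, value -0.02). Array weights ended the immediate early (0.221) and oligodendrocyte (0.121) calls, composition covariates the striatal (0.407) and oligodendrocyte (0.891) ones, and inflammation had fewer than 3 genes above the 75th percentile. With limma 0 genes passed (251 unadjusted), and the S-scores gave 0 (550 unadjusted), or 0 against 0. Apart from predicted genes, nearest to passing in either direction were Ctrl (0.19), Fhit (0.15), Acyp1 (-0.18) and the death receptor Fas (-0.24).

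A day after the pump came out, C57BL/6J nicotine mice had higher values of striatal dopamine signalling genes than saline mice (camera adjusted p = 7.2e-04, and adjusted p = 0.649 with an estimated correlation). Their mean was 0.12 ± 0.12 (n = 6) against -0.01 ± 0.14 (n = 6), and 14 of 15 members were higher. The phosphodiesterase Pde10a stood at 0.18, the dopamine receptor Drd1 at 0.22, the adenylyl cyclase Adcy5 at 0.21 and Rgs9 at 0.20. Cortical excitatory neuron markers, at the other end of the tissue component, were lower in 11 of 12 members by -0.16 on average (-0.07 ± 0.28 against 0.09 ± 0.18). Interferon response genes were lower in 12 of 13 members by -0.09 on average (adjusted p = 0.0179, and adjusted p = 0.649 with an estimated correlation), with Rtp4 at -0.23, Ifit2 at -0.15, Trim30a at -0.09 and Ifitm3 at -0.18. Oligodendrocyte genes were lower in 13 of 14 by -0.13 on average (adjusted p = 0.00697, and adjusted p = 0.649 with an estimated correlation), with Mog at -0.28, Nkx6-2 at -0.18, Mobp at -0.24 and Enpp2 at -0.21.

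Striatal dopamine signalling had 5 of 6 mice above the saline mean and passed camera in all 12 repeats without 1 mouse. For interferon 6 of 6 mice lay under the saline mean, and for oligodendrocytes 5 of 6. Cortical markers had adjusted p = 0.0510 and did not pass. With composition covariates the striatal (0.0614) and oligodendrocyte (0.885) calls were lost, and above the 75th percentile interferon had fewer than 3 genes. The interferon call was lost without C57BL/6J withdrawal nicotine mouse 5 (0.119) or saline mouse 3 (0.137) or 4 (0.0752). The oligodendrocyte call was lost without nicotine mouse 1 (0.0895) or 4 (0.0952) or saline mouse 3 (0.0784) or 4 (0.0752). Limma called 0 of 9596 genes, with 287 at an unadjusted p under 0.05 (108 higher, 179 lower), or 192 higher and 116 lower with arrays centred on their median. The S-scores gave 0 (762 unadjusted), and 1 against 0, the T cell receptor segment Trav9d-4 (mean score -1.85, named after its value was seen). On simulated data without an effect that test called 200.8 of 9596 genes on average in this contrast. Values that did not pass were lower for the histone variant H2afy3 (-0.27, SE 0.07, 6 of 6 mice), Mrm3 (-0.22), Nipal4 (-0.26), Snx33 (-0.30), Tspan15 (-0.20), Reep4 (-0.16), the heat shock gene Hspa1b (-0.38), Ccdc71 (-0.19), R3hcc1 (-0.15) and Spcs2 (-0.17). On the higher side they were Olfr1321 (0.28), AY074887 (0.19), Ighv2-9-1 (0.45), Olfr690 (0.26), Sry (0.28), the mitochondrial COX1 (0.13), Vmn2r44 (0.20), Hmga2 (0.13), Zfp827 (0.14) and Isoc2b (0.15). Of heat shock genes, 1 passed adjusted over the list alone and 0 over all genes tested. Fixed genes ran from Chrna7 (-0.06) to Drd1 (0.22), with 0 of 7 passing and 0 at an unadjusted p under 0.05, and by S-score 0 of 16 and 0. The interval of 96.9% of genes lay within 0.5 of 0.

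In DBA/2J mice a day after nicotine no gene list passed camera, 0 lists with an estimated correlation, 0 with fry and 0 with the exact permutation. The permutation had 462 splits, too few for a single list to pass after adjustment over 41 lists. Its lowest adjusted p was 0.444. Other settings gave 10 lists (all features), 3 (no filter) and 1 each (array weights, composition covariates, cyclic loess). Leaving out 1 mouse gave 3 lists without nicotine mouse 5, 2 without nicotine mouse 4 or saline mouse 6, and 1 without nicotine mouse 2. By S-score 6 lists passed camera, among them synaptic vesicle release (adjusted p = 1.9e-06) and potassium channels (adjusted p = 5.9e-05), both higher, and 0 with an estimated correlation. Limma called 0 of 9596 genes (lowest adjusted p = 0.812), with 523 at an unadjusted p under 0.05 (340 higher, 183 lower), or 114 higher and 391 lower with arrays centred on their median. The S-scores gave 0 (1661 unadjusted), or 224 against 0. Values that did not pass included the ubiquitin ligase gene Siah3 (0.46, SE 0.12, 5 of 5 mice), Lrp12 (0.19), Gdpd1 (0.23), the casein kinase Csnk1d, a kinase of the circadian clock (0.17), Zdhhc1 (0.22), Zfp143 (0.21), Trim30a (0.22), Wbp1l (0.21), Zadh2 (0.25) and Acad8 (0.21). Lower values were those of the claudin Cldn24 (-0.32, SE 0.08, 5 of 5 mice), RP23-258B4.1 (-0.47), Olfr592 (-0.29), Slc22a12 (-0.15), the growth factor Vegfd (-0.23), Gpha2 (-0.22), Pate12 (-0.30), AY074887 (-0.19) and the Y-linked demethylase Kdm5d (-0.30). Of the saline mice in that Kdm5d comparison, mice 5 and 1 had 10.5 and 10.2 (log2), and the other 4 between 9.70 and 9.82. Of interferon genes, 1 passed adjusted over the list alone and 0 over all genes tested. Fixed genes ran from Th (-0.01) to Drd2 (0.08), with 0 of 7 passing and 0 at an unadjusted p under 0.05, and by S-score 0 of 16 and 1. Fitted with these 2 groups alone, 3 predicted genes of the Y chromosome passed, Gm20925 (0.77, adjusted p = 0.00636), Gm21268 and Gm20936 (each 0.61, adjusted p = 0.00628), named after their values were seen. Gm21268 and Gm20936 had identical values, so they may not be separate measurements. The interval of 96.3% of genes lay within 0.5 of 0.

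The strains' responses in withdrawal differed in cholesterol biosynthesis genes, by 0.15 on average with 14 of 15 members positive (adjusted p = 0.855 with an estimated correlation), among them Dhcr7 (0.27), Stard4 (0.17) and Nsdhl (0.22). They also differed in blood cell genes, by -0.39 on average (adjusted p = 0.855 with an estimated correlation), among them the haem enzyme gene Alas2 (-0.31) and the globin gene Hbb-bt (-0.58). Camera gave both lists adjusted p = 0.0456, and the calls passed in 11 and 13 of 23 repeats without 1 mouse. The cholesterol call was lost without C57BL/6J nicotine mouse 1 (0.117), C57BL/6J saline mouse 1 (0.0683), 2 (0.0502), 3 (0.132), 4 (0.0542) or 6 (0.0885), DBA/2J nicotine mouse 1 (0.174), 3 (0.0746) or 4 (0.0601), or DBA/2J saline mouse 1 (0.14), 4 (0.264) or 5 (0.0791). The blood cell call was lost without C57BL/6J nicotine mouse 1 (0.123) or 4 (0.0848), C57BL/6J saline mouse 2 (0.0502), 4 (0.0542) or 6 (0.0933), DBA/2J nicotine mouse 3 (0.0746), 4 (0.0888) or 5 (0.0504), or DBA/2J saline mouse 4 (0.064) or 5 (0.0791). Above the 75th percentile (0.180), with quantile normalization (0.0527) or with composition covariates (0.793) the cholesterol call was lost. The blood cell call was lost with no filter (0.0996), above the 75th percentile (0.0998), with all features (0.170), median-centred arrays (0.0692), quantile normalization (0.0828), cyclic loess (0.0641), array weights (0.131) or covariates (0.0751). With limma 0 of 9596 genes differed (lowest adjusted p = 0.604), with 676 at an unadjusted p under 0.05 (448 higher, 228 lower). With arrays centred on their median 164 were higher and 522 lower. The S-scores gave 0 (1835 unadjusted), or 483 against 0. Cldn24 (-0.47), H2afy3 (0.42), Fn3krp (0.43) and the quinone reductase Nqo1 (0.51) were among the smallest p and did not pass. Without DBA/2J nicotine mouse 5 limma called 1 predicted gene, Gm16139 (-0.70, adjusted p = 0.0420), named after its value was seen. Of interferon and oxidative stress genes, 1 each passed adjusted over the list alone and 0 over all genes tested. Averaged over the strains, striatal dopamine signalling was higher in withdrawal in 15 of 15 members, by 0.10, with Adcy5 at 0.16 and Drd1 at 0.14. That list passed camera with adjusted p = 5.5e-04, and adjusted p = 0.896 with an estimated correlation. The exact permutation of list means, with 426888 splits, passed 0 lists in this average (lowest adjusted p = 0.940). By camera striatal dopamine signalling passed in 23 of 23 repeats without 1 mouse. The value was 0.13 in C57BL/6J and 0.08 in DBA/2J, where it was 0.03 without nicotine mouse 5, 0.05 without nicotine mouse 4 and 0.04 without saline mouse 6. With limma 0 genes passed in that average (171 unadjusted), and the S-scores gave 0 (682 unadjusted), or 0 against 0.

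Across genes, the strains' responses tended to opposite signs. The correlation of C57BL/6J and DBA/2J differences across 9596 genes was -0.27 (Spearman -0.21) in chronic treatment and -0.34 (Spearman -0.30) in withdrawal, and 38.5% and 39.2% of genes had the same sign. In chronic treatment the median of all genes differed by -0.03 in C57BL/6J and 0.02 in DBA/2J, which lowers that share, and with arrays centred on their median it was 43.1%, and 39.1% in withdrawal. Genes are not independent replicates, so the mice were permuted between drugs within each group. The permutation p was 0.139 and 0.0396, and 0.277 and 0.158 after adjustment over the 4 correlations computed. Chronic and withdrawal differences correlated at 0.12 in C57BL/6J (permutation p = 0.436) and 0.10 in DBA/2J (permutation p = 0.604), with adjusted values of 0.581 and 0.604. These correlations depend on single mice and on settings. Without C57BL/6J chronic saline mouse 3 the C57BL/6J value was -0.0066, and with array weights 0.0020. The DBA/2J value was -0.0132 without withdrawal nicotine mouse 5, -0.0036 without withdrawal nicotine mouse 4, -0.00058 without withdrawal saline mouse 6 and -0.010 with array weights. Between strains in chronic treatment the value was -0.43 without C57BL/6J saline mouse 3, -0.11 without C57BL/6J saline mouse 6 and -0.14 with all features. In withdrawal it was -0.42 without DBA/2J nicotine mouse 5, -0.22 without DBA/2J nicotine mouse 1 and -0.15 with all features.

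The response in withdrawal was then set against that in chronic treatment within each strain. In C57BL/6J the withdrawal response was higher for oxidative phosphorylation by 0.12 (29 of 31 members, Cox5a 0.29 and Atp5o 0.20) and for blood cells by 0.47 (each adjusted p = 0.709 with an estimated correlation). It was lower for oligodendrocytes by -0.12 (Enpp2 -0.41), their precursors by -0.14 (9 of 9 members, Bmp4 -0.27), meninges and fibroblasts by -0.36, cortical neurons by -0.18 (Rorb -0.33) and interferon genes by -0.07 (Ifit2 -0.24). With an estimated correlation the adjusted p = 0.301 for the precursors and 0.709 for the other 4 of these. Camera gave adjusted p = 3.2e-04, 0.0117, 0.00554, 0.00225, 0.0103, 0.00857 and 0.0420 in that order. These differences include the chronic responses, which were -0.11 for oxidative phosphorylation, 0.05 for the precursors and 0.28 for the meninges. In withdrawal itself, of these lists only oligodendrocytes and interferon genes passed camera. Oxidative phosphorylation and the precursors passed in 23 of 23 repeats without 1 mouse. The oligodendrocyte call was lost without chronic nicotine mouse 1 (0.146, value -0.06) or chronic saline mouse 5 (0.0889, value -0.07), and its value was -0.20 without chronic nicotine mouse 4 or chronic saline mouse 4. That of the meninges was lost without chronic nicotine mouse 4 (0.0829, value -0.23), withdrawal nicotine mouse 5 (0.0648) or withdrawal saline mouse 2 (0.0585), and that of cortical neurons without chronic nicotine mouse 2 (0.052), chronic saline mouse 6 (0.169, value -0.07) or withdrawal nicotine mouse 1 (0.0688, value -0.12), and the cortical value was -0.29 without chronic saline mouse 3. The blood cell call was lost without chronic nicotine mouse 2 (0.0648) or 5 (0.0728), chronic saline mouse 2 (0.119) or 3 (0.108), withdrawal nicotine mouse 1 (0.124) or withdrawal saline mouse 6 (0.0582). The interferon call was lost without chronic nicotine mouse 1 (0.0724) or 3 (0.438, value -0.03), chronic saline mouse 1 (0.214), 3 (0.0764), 4 (0.0672) or 6 (0.0993), withdrawal nicotine mouse 2 (0.0596), 5 (0.127) or 6 (0.0624), or withdrawal saline mouse 3 (0.167, value -0.05) or 4 (0.0536). With no filter the calls for interferon (0.331), oligodendrocytes (0.0520), blood cells (0.0820) and cortical neurons (0.0620) were lost, and with all features the same 4 (0.367, 0.0594, 0.0501 and 0.0691). With composition covariates these 4 were lost too (0.125, 0.565, 0.0586 and 0.537). Interferon was also lost with median-centred arrays (0.0604), quantile normalization (0.119) or cyclic loess (0.106), meninges with quantile normalization (0.0557) and blood cells with array weights (0.108). Above the 75th percentile the precursors were lost (0.130), and interferon and meninges had fewer than 3 genes. Limma called 0 genes (240 unadjusted), and the S-scores gave 0 (474 unadjusted), or 0 against 0.

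In DBA/2J the withdrawal response was higher than the chronic response for immediate early genes by 0.31 (Dusp6 0.55, Egr1 0.45), oligodendrocytes by 0.23 (14 of 14 members, Trf 0.49) and cortical neurons by 0.37 (Slc17a7 0.86), each with adjusted p = 0.639 with an estimated correlation. It was also higher for synaptic vesicle release by 0.14 (the synapsin Syn1 0.23), cholesterol biosynthesis by 0.12 (15 of 15 members, Dhcr7 0.22) and endothelium and pericytes by 0.14 (9 of 9 members), again with adjusted p = 0.639 with an estimated correlation. Camera gave adjusted p = 0.00107, 9.1e-05, 0.00309, 0.00364, 0.00402 and 0.00883 in that order. These differences include the chronic responses, which were -0.25 for immediate early genes, -0.19 for oligodendrocytes and -0.23 for cortical neurons. They are not separate rises in withdrawal, where no list passed camera in DBA/2J. Immediate early genes, oligodendrocytes and vesicle release passed in 23 of 23 repeats without 1 mouse. Cortical neurons were lost without withdrawal saline mouse 4 (0.0533), endothelium without chronic nicotine mouse 4 (0.111) or withdrawal nicotine mouse 2 (0.0837), and cholesterol without chronic nicotine mouse 1 (0.0599), withdrawal nicotine mouse 1 (0.0748) or withdrawal saline mouse 4 (0.0652). With composition covariates only immediate early genes still passed (cholesterol, oligodendrocytes and cortical neurons each 0.976, vesicle release 0.415, endothelium 0.0644), and endothelium was lost above the 75th percentile (0.155). Of oligodendrocyte precursor genes, 1 passed adjusted over the list alone and 0 over all genes tested. Limma called 0 genes (359 unadjusted), and the S-scores gave 0 (1022 unadjusted), or 12 against 0.

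Saline mice without the pump were compared with saline mice that kept it, and of 100 splits of the same mice, the real one among them, 46 in C57BL/6J and 11 in DBA/2J gave as many lists. In C57BL/6J, mice without the pump had higher oligodendrocyte genes in 14 of 14 members, by 0.18 on average (adjusted p = 0.234 with an estimated correlation), with Opalin at 0.44, Mog at 0.39 and Cnp at 0.23. Their glucocorticoid responsive genes were lower in 13 of 14 members by -0.17 (adjusted p = 0.234 with an estimated correlation), or by -0.10 without chronic saline mouse 1, with the cell cycle inhibitor Cdkn1a at -0.32, Fkbp5 at -0.15 and the connexin Gjb6 at -0.31. Blood cell genes were lower by -0.45 (Hbb-bt -0.75, Alas2 -0.36), markers of the olfactory tubercle and islands of Calleja by -0.35 (the neuropeptide Nts -0.73, Drd3 -0.49), cholinergic neurons by -0.18 (Isl1 -0.41, Chat -0.19) and inflammation by -0.15 (-0.07 without chronic saline mouse 1). For these 4 the adjusted p = 0.234 with an estimated correlation, or 0.346 for cholinergic neurons. Camera gave adjusted p = 3.2e-08, 3.5e-05, 2.1e-04, 9.2e-04, 0.0098 and 0.0285 in that order, with 6, 5, 6, 6, 5 and 6 of the 6 mice without the pump past the mean of those with it. The first 4 passed in 12 of 12 repeats without 1 mouse. The cholinergic call was lost without chronic saline mouse 1 (0.0507), 2 (0.0563) or 6 (0.0787) or withdrawal saline mouse 6 (0.0538). That of inflammation was lost without chronic saline mouse 1 (0.221), 2 (0.0628) or 3 (0.0591) or withdrawal saline mouse 5 (0.0742) or 6 (0.108). Composition covariates ended the oligodendrocyte (0.630), cholinergic (0.0925) and inflammation (0.0746) calls. Inflammation was also lost with all features (0.0550) or only these groups fitted (0.0579), and above the 75th percentile it and cholinergic neurons had fewer than 3 genes. Adjusted over the list alone, 2 oligodendrocyte, 4 blood cell and 3 olfactory tubercle genes passed, where 0 did over all genes tested. With limma 0 of 9596 genes passed (359 unadjusted), and the S-scores hold no saline mice. Of genes other than predicted ones, the insulin receptor substrate Irs2 came nearest and did not pass (-0.48, SE 0.13, limma adjusted p = 0.998), lower in 6 of 6 mice.

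In DBA/2J, saline mice without the pump had higher oxidative phosphorylation genes in 28 of 31 members, by 0.08 on average, with Cox8a and Cox4i1 each at 0.22 (adjusted p = 0.776 with an estimated correlation). Proteasome genes were higher by 0.05 (Psmd11 0.11, Psmb1 0.15), again with adjusted p = 0.776 with an estimated correlation. Extracellular matrix genes were lower by -0.09 (Col4a1 -0.08), astrocyte markers by -0.08 (Mlc1 -0.14), endothelium by -0.08 (Cldn5 -0.17) and meninges by -0.31 (Ogn -0.79). With an estimated correlation the adjusted p = 0.628 for the matrix and 0.776 for the other 3 of these. Camera gave adjusted p = 0.00133, 0.0143, 0.00799, 0.0132, 0.0257 and 0.0132 in that order, with 5, 5, 6, 4, 4 and 6 of the 6 mice without the pump past the mean of those with it. Oxidative phosphorylation passed in 12 of 12 repeats without 1 mouse. Without withdrawal saline mouse 1 the calls for matrix (0.0562), astrocytes (0.182, value -0.04), endothelium (0.291, value -0.05) and meninges (0.182) were lost, and without withdrawal saline mouse 3 those for the proteasome (0.223) and astrocytes (0.0625). Chronic saline mouse 3 carried the calls for the proteasome (0.0790 without it), endothelium (0.108) and meninges (0.105), mouse 5 those for the proteasome and endothelium (each 0.0531), mouse 4 that for the proteasome (0.0504), and withdrawal saline mouse 4 that for endothelium (0.0577). Above the 75th percentile only oxidative phosphorylation still passed (proteasome, astrocytes and endothelium each 0.0691, matrix 0.104), and meninges had fewer than 3 genes. With no filter matrix (0.358), astrocytes (0.0769), endothelium (0.143) and meninges (0.0710) were lost, and with all features matrix (0.1999) and endothelium (0.0928). The proteasome and endothelium calls were lost with quantile normalization (0.0933 and 0.0628), cyclic loess (0.0782 and 0.0559) or composition covariates (0.0768 and 0.105), and that of the meninges with covariates (0.105). With limma 0 of 9596 genes passed, with 389 at an unadjusted p under 0.05. Imp3 (0.40), Zhx1 (0.12) and the lamin Lmnb1 (-0.16) were among those nearest to passing.

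**Figure D2:**
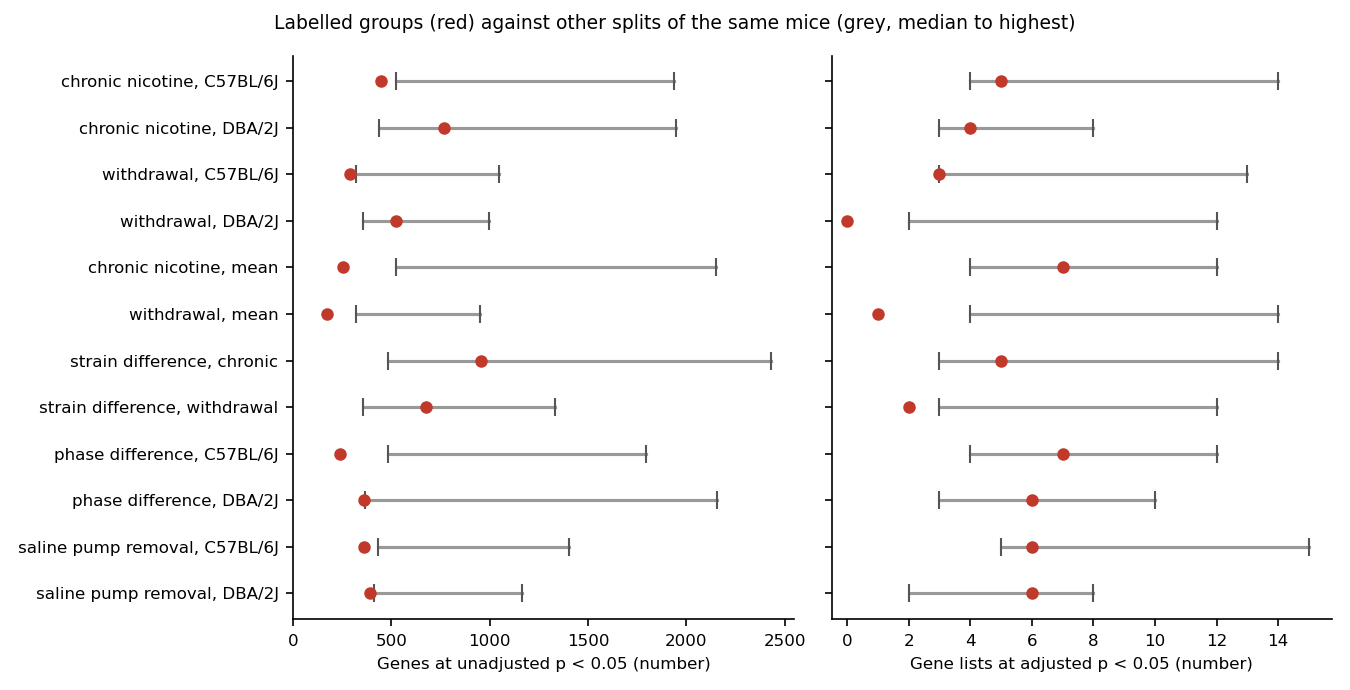
Number of genes at an unadjusted p under 0.05 (left) and of gene lists at an adjusted p under 0.05 (right) in 12 contrasts, with red points for the real groups and grey bars from the median to the highest of the other splits of the same mice. The real counts lie inside the grey bars or below them, as with 449 genes for chronic nicotine in C57BL/6J, where another split reached 1940.

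The strains themselves differed widely under saline. Of 9596 genes, 3052 (31.8%) passed with limma, 1193 higher and 1859 lower in DBA/2J, and 84 differed over 2-fold (27 higher, 57 lower). The scavenger receptor gene Stab2 (TC1000002629.mm.1, chromosome 10, 86841198 to 87008025) was highest above C57BL/6J, at 9.45 ± 0.67 (SD, n = 12) against 6.06 ± 0.10 (n = 12), a difference of 3.40 (SE 0.23, adjusted p = 1.7e-16). The C57BL/6J value lies under the lowest array median of non-control features, 6.30, so it may be near background and the size is uncertain. The same holds for the DBA/2J value of Pttg1 (6.20) below. Whether these sizes are too small or too large was not tested. Others far higher in DBA/2J were the centrosome gene Sfi1 (2.04), the malonyl-CoA decarboxylase Mlycd (1.76), the riboflavin kinase Rfk (1.75), Zfp949 (1.66), Pcdhb2 (1.51), the mitochondrial carrier Ucp2 (1.40), Ndn (1.37) and the pseudogenes Pisd-ps3 (1.69) and Pisd-ps1 (1.37). Far lower were the securin gene Pttg1 (-1.99, adjusted p = 3.2e-31), Zfp125 (-1.92), Trav9-4 (-1.69), Erdr1 (-2.22) and a group with several similar copies, AC087559.1 (-3.23), CR974586.7 (-3.21), Fam205a2 (-2.44), Ccl21a (-2.31) and Ccl21b (-2.25). The array cannot separate similar copies, so which copy differs is unknown.

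Genes with a known strain difference were read as a check. Glo1, the glyoxalase with extra copies in DBA/2J (TC1700001805.mm.1, chromosome 17, 30591250 to 30612659), differed by 1.24 (SE 0.043, adjusted p = 1.7e-26), and 46 of 46 arrays lay on their own strain's side. Myo5a, which carries the dilute mutation of DBA/2J, was lower by a small step (-0.13, SE 0.033, adjusted p = 0.00133), and after another quantile normalization it was -0.07 and did not pass. Nnt, part of which is deleted in C57BL/6J, did not differ (-0.0055, SE 0.036, adjusted p = 0.925), its sign changed with several settings, and which part of the gene its probes cover is not given in the sources used here. The other check genes have no per-array values. The direction split depends on scale. Of the called genes 39.1% were higher in DBA/2J as deposited, 53.3% with arrays centred on their median, 52.5% after quantile normalization, 49.0% after cyclic loess and 50.1% with no filter. No gene list passed camera between strains: 0 with the preset and 0 with the estimated correlation, while fry, which asks whether a list's genes move on balance, passed 19.

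**Figure D3:**
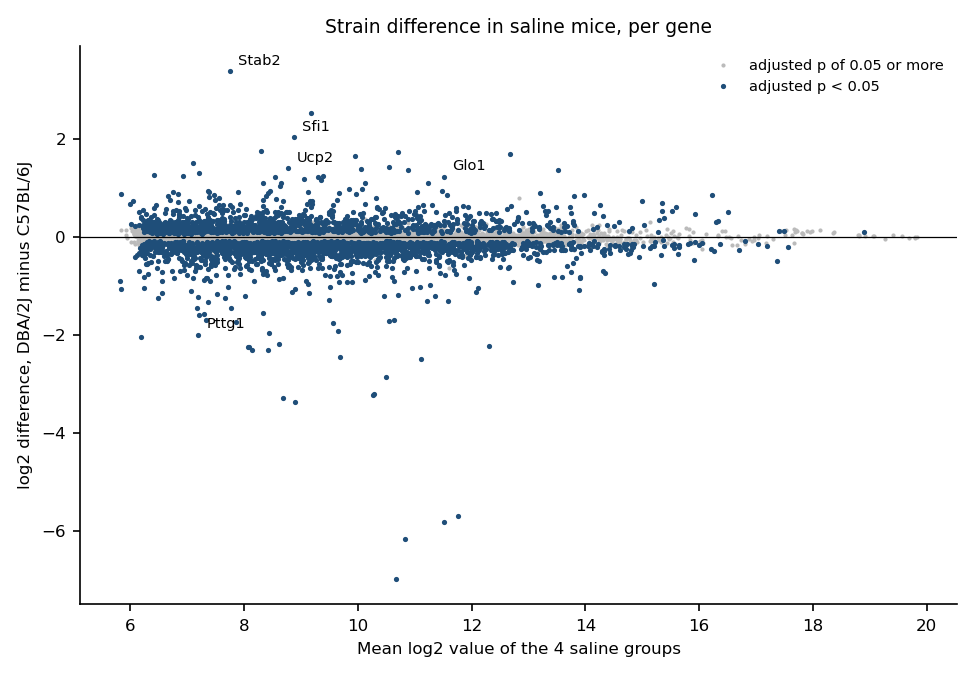
Log2 difference DBA/2J minus C57BL/6J of every tested gene among saline mice (12 per strain) against its mean log2 value, with called genes marked and 5 of them named. Stab2 stands highest at 3.40, an uncertain size since its C57BL/6J value of 6.06 lies under the lowest array median of 6.30, and the lowest points are predicted genes.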

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

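In this part, the test of tissue composition on the glucocorticoid pattern was set down before its result was seen, and the counts of other splits and all other tests of an explanation were set down only after the result was seen. The fits with composition covariates and with each mouse left out were planned, but their use to explain the correlation in withdrawal was chosen after.

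Glucocorticoid responsive genes were lower in C57BL/6J chronic nicotine mice by -0.18 on average, and a technical or handling source was weighed. With 3 covariates, for oligodendrocyte, cortical neuron and choroid plexus markers, the mean difference was -0.18 as well. This argues against these 3 as the whole cause. Other tissue, such as blood or the olfactory tubercle, was not adjusted for and stays open. The saline mice without the pump lay lower than those with it by -0.17, a share of 0.94 of the nicotine difference, with an exact p of 0.0823. So the difference may come from saline mice with the pump standing high (C57BL/6J chronic saline mouse 1 at 0.49, without which the nicotine and pump differences were -0.11 and -0.10) as much as from nicotine, and the 6 against 6 saline mice do not decide it. A hormonal effect of nicotine stays open as a biological explanation, untested for want of a hormone measurement.

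Of the genes that passed between strains under saline, 60.9% were lower in DBA/2J (44.2%, 66.9% and 68.9% in 3 equal bins from low to high mean value), and the source of this tilt was weighed. Centring arrays on their median gave 46.7% and kept the rise (31.2% to 55.4%), and cyclic loess gave 51.0% without it (53.4% to 49.2%), so scaling that varies with intensity may contribute, though loess levels such a trend whatever its source. Background on the DBA/2J arrays was not decided, since the control features differed by 0.02 with an upper bound of 0.08, and the dim genes left out shifted by 0.06 (719 of 797 called were higher in DBA/2J). Among genes over 2-fold after cyclic loess, 65.5% (55 of 84, 95% interval 54.3% to 75.5%) were lower in DBA/2J, as probe mismatches with that strain could give. That interval treats genes as independent, which they are not, so it may be too narrow and does not measure the spread over mice. By bins of probe number from few to many, 47.8%, 67.6% and 66.3% of all called genes were lower as deposited and 43.2%, 58.6% and 50.8% after cyclic loess. Without probe sequences mismatches and true expression both stay open.

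In withdrawal the nicotine differences of the strains correlated across genes at -0.34. Of 100 relabellings of the mice, 3 gave a correlation as far from 0, and after adjustment over 4 correlations (0.158) chance could not be excluded. With covariates for composition the correlation was -0.26, and the value nearest 0 with 1 mouse left out was -0.22 (without DBA/2J withdrawal nicotine mouse 1). The correlation thus stayed negative, but most relabellings of the mice gave values between -0.275 and 0.236, a range that holds -0.26 and -0.22. Those relabellings used all mice and no covariates, so their range is only a rough reference for the values from the other fits. These values therefore cannot decide whether composition or a single mouse is the whole cause, and each stays open. A response that differs by strain may remain, as a hypothesis that these mice do not settle.

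For each contrast, 100 splits of the same mice, the real one among them, were fitted to see how often others gave as many genes at an unadjusted p under 0.05 or as many lists at an adjusted p under 0.05. Chance was not excluded for any nicotine or pump contrast. Chronic nicotine in C57BL/6J gave 449 genes (59 splits as many, highest other 1940) and 5 lists (40 splits, highest 14). In DBA/2J it gave 768 genes (21 splits, highest 1947) and 4 lists (42 splits, highest 8). Withdrawal gave 287 genes (59 splits, highest 1049) and 3 lists (64 splits, highest 13) in C57BL/6J, and 523 genes (19 splits, highest 994) and 0 lists (100 splits, highest 12) in DBA/2J. The mean over strains gave 251 genes (89 splits, highest 2153) and 7 lists (21 splits, highest 12) in chronic treatment, and 171 genes (85 splits, highest 950) and 1 list (88 splits, highest 14) in withdrawal. The strain difference of the response gave 955 genes (13 splits, highest 2433) and 5 lists (42 splits, highest 14) in chronic treatment, and 676 genes (9 splits, highest 1330) and 2 lists (77 splits, highest 12) in withdrawal. The phase difference gave 240 genes (88 splits, highest 1793) and 7 lists (29 splits, highest 12) in C57BL/6J, and 359 genes (53 splits, highest 2157) and 6 lists (18 splits, highest 10) in DBA/2J. Pump removal gave 359 genes (68 splits, highest 1404) and 6 lists (46 splits, highest 15) in C57BL/6J, and 389 genes (52 splits, highest 1162) and 6 lists (11 splits, highest 8) in DBA/2J. Why some splits call several times the real count was not tested. For the strain contrast, at an adjusted p under 0.05, the real split gave 3052 genes and the highest other 373, 1 split in all with as many, so chance was excluded, while its 0 lists were matched by 100 splits (highest 16).

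A sample stood far from the others of its group in 15 of 384 groups of values (3.91%), where chance marks about 1 in 20. The ratio of the gap to the group's range was 0.712 for inflammation genes in C57BL/6J chronic saline mouse 1 (0.44 against -0.03 for the nearest mouse). It was 0.754 for Ctla2a (8.46 against 7.48) and 0.696 for Ucp2 (8.68 against 8.17) in the same mouse. In C57BL/6J chronic saline mouse 3 it was 0.724 for Sik3 (12.3 against 12.5), and in chronic nicotine mouse 5 it was 0.823 for Defa39 (7.30 against 7.08). Among C57BL/6J withdrawal mice it was 0.659 for interferon genes in nicotine mouse 5 (-0.16 against -0.08), 0.654 for Olfr1321 in nicotine mouse 2 (6.27 against 6.56) and 0.719 for Ccl21a in saline mouse 6 (10.03 against 9.57). Among DBA/2J chronic saline mice it was 0.711 for Fam50b in mouse 5 (7.18 against 6.90), 0.688 for Pik3c2a in mouse 3 (9.87 against 10.3) and 0.697 for Sfi1 in mouse 6 (9.67 against 9.89). In DBA/2J withdrawal nicotine mouse 4 it was 0.794 for Lrp12 (10.9 against 10.8) and 0.837 for Zfp143 (10.1 against 10.2). In DBA/2J withdrawal saline mouse 3 it was 0.802 for Zdhhc1 (9.73 against 9.97) and 0.626 for Npm3 (7.08 against 6.87).

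The response to nicotine differed between groups in 20 calls by camera, over 4 contrasts, and a list can hold more than 1 call. Between strains in chronic treatment the adjusted p was 5.2e-05 for oligodendrocytes and 0.00575 for immediate early genes, oxidative phosphorylation, meninges and fibroblasts and cortical neurons. Between strains in withdrawal it was 0.0456 for cholesterol biosynthesis and for blood cells. Between phases in C57BL/6J it was 3.2e-04 for oxidative phosphorylation, 0.00225 for oligodendrocyte precursors, 0.00554 for oligodendrocytes, 0.00857 for cortical neurons, 0.0103 for meninges and fibroblasts, 0.0117 for blood cells and 0.0420 for interferon genes. Between phases in DBA/2J it was 9.1e-05 for oligodendrocytes, 0.00107 for immediate early genes, 0.00309 for cortical neurons, 0.00364 for synaptic vesicle release, 0.00402 for cholesterol biosynthesis and 0.00883 for endothelium and pericytes. Only 6 of the calls passed in every repeat without 1 mouse (oligodendrocytes between strains in chronic treatment, oxidative phosphorylation and precursors between phases in C57BL/6J, and immediate early genes, oligodendrocytes and vesicle release between phases in DBA/2J). None passed with an estimated correlation, where the lowest adjusted p was 0.301.

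Features without a gene name, which no comparison of the genes uses, also differed between the strains under saline: 3650 of 24877 passed with limma.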

How the results depend on the processing

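The tests of S-scores against 0, the exact permutation of list means and cyclic loess were chosen only after the data were seen, and the other alternatives were planned. Single genes in the nicotine and pump contrasts stayed at 0 by limma under the filters, scalings, weights, variance moderation, covariates and mouse-number blocks tried, apart from the values given here. List counts moved with most settings, and the cause was not tested except where stated. With no filter 50.1% of the genes called between strains were higher in DBA/2J, against 39.1%, since of the 797 called dim genes that the filter leaves out 719 were higher. Signal near background limits the size of a difference that a dim gene can show.

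With no filter the lists passing camera numbered 9 in C57BL/6J withdrawal, 3 in DBA/2J withdrawal, 2 in the mean of withdrawal, 6 for the strain difference in withdrawal, 11 and 2 for pump removal in C57BL/6J and DBA/2J, and 6 between strains. Above the 75th percentile, where fewer genes are tested, they numbered 1 in C57BL/6J chronic treatment, 2 in the mean of withdrawal, 3 and 0 for the strain difference in chronic treatment and withdrawal, and 1 for pump removal in DBA/2J, and 1995 genes passed between strains. With all features, named or not, they numbered 8 and 7 in chronic treatment (C57BL/6J, DBA/2J), 12 and 10 in withdrawal, 2 in the mean of withdrawal, 10 and 17 for the strain difference in chronic treatment and withdrawal, and 12 between strains. There 6824 features passed between strains, 1 unnamed feature passed for the strain difference in withdrawal (-0.82, adjusted p = 0.0267), and the strains' withdrawal responses correlated at -0.15.

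Centring arrays on their median gave 8 lists in C57BL/6J withdrawal and 2 and 4 for the strain difference in chronic treatment and withdrawal, with Nnt at 0.025. Quantile normalization gave 6, 1 and 0 in that order, with Nnt at 0.029 and Myo5a at -0.071, which no longer passed. Cyclic loess gave 7, 1 and 4, with 1 list in DBA/2J withdrawal and Nnt at 0.031. Array weights gave 6 lists in C57BL/6J and 1 in DBA/2J withdrawal, 2 in their mean, 4 for the strain difference in withdrawal and 10 for the phase difference in DBA/2J, and the chronic and withdrawal responses of DBA/2J correlated at -0.010. The 3 composition covariates, 2 of which are the means of the oligodendrocyte and cortical lists, gave 2 lists in DBA/2J chronic treatment, 1 in DBA/2J withdrawal, 2 in the mean of withdrawal, 2 and 0 for the strain difference in chronic treatment and withdrawal, 3 for the phase difference in C57BL/6J and 3 for pump removal in DBA/2J. With them 1864 genes passed between strains, Nnt stood at 0.065 and Th in DBA/2J withdrawal at 0.0071. Fitting only the groups compared gave 9 lists in C57BL/6J withdrawal, 3 in the mean of withdrawal and 3 genes in DBA/2J withdrawal.

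The authors' S-scores tested against 0 gave 5 and 113 genes in chronic treatment (C57BL/6J, DBA/2J), 1 and 224 in withdrawal, 16 and 483 for the strain difference and 12 for the phase difference in DBA/2J. Leaving out the spread of the saline mice produces false calls, 102.3 to 200.8 on average in simulated data without an effect on 9596 genes, and the number expected of the 25802 genes scored here was not simulated. Camera with an estimated correlation gave 0 lists in all 11 contrasts that had any, and fry gave 0 in these and 19 between strains. The exact permutation gave 0 lists in C57BL/6J chronic treatment, C57BL/6J withdrawal, both means and both pump contrasts, and 2 in DBA/2J chronic treatment. Outside the means it had 462 or 924 splits, too few for a single list to pass after adjustment over 41 lists. Those counts of 0 therefore say little. With the mouse number as a block, 3072 genes (fixed) and 3050 genes (random) passed between strains and 0 elsewhere. Mice of the same number correlated at -0.35 to 0.32, and the correlation fitted for the random block was -0.0020. In DBA/2J pump removal 3 of 6 pairs lay over 0.1, with a median of 0.05 against 0.03 for other pairs. In the other contrasts checked the median of same-numbered pairs lay below that of other pairs. No general pairing by number was thus seen.

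With 1 mouse left out at a time, lists numbered 2 to 7 in C57BL/6J chronic treatment (2 without saline mouse 1), 3 to 7 in DBA/2J chronic treatment, 1 to 11 and 0 to 3 in withdrawal, 5 to 10 and 1 to 3 in the means, 3 to 8 and 0 to 6 for the strain difference, 5 to 12 and 5 to 9 for the phase difference, and 4 to 11 and 2 to 8 for pump removal. Genes numbered 0 to 5 for the strain difference in chronic treatment, 0 to 1 in withdrawal and 0 to 0 in the other nicotine and pump contrasts, and 2833 to 3338 between strains, where lists stayed at 0. Glo1 ranged from 1.22 to 1.26, Myo5a from -0.15 to -0.12 and Nnt from -0.030 to 0.011. Nnt was above 0 without C57BL/6J chronic saline mouse 6 (0.010), C57BL/6J withdrawal saline mouse 3 (0.0039), DBA/2J chronic saline mouse 2 (0.011) or DBA/2J withdrawal saline mouse 5 (0.0019). Th in DBA/2J withdrawal was above 0 without nicotine mouse 1 (0.024), 2 (0.041) or 3 (0.0093) or saline mouse 2 (0.0078) or 4 (0.010), and its lowest value was -0.094 (without nicotine mouse 4). Chrna7 in C57BL/6J chronic treatment ranged from -0.014 (without saline mouse 1) to 0.088. The correlation of the strains' responses ranged from -0.43 to -0.11 in chronic treatment and from -0.42 to -0.22 in withdrawal. That between phases ranged from -0.0066 (without chronic saline mouse 3) to 0.203 in C57BL/6J. In DBA/2J it ranged from -0.0132 (without withdrawal nicotine mouse 5) to 0.218, and was -0.0036 without withdrawal nicotine mouse 4 and -0.00058 without withdrawal saline mouse 6.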

Other observations

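In this part the genes were chosen by the naming rule except where stated, and the comparison of Y-linked genes was chosen only after the result was seen. Genes of chromosomes 1 to 6 are known here almost only by the authors' S-scores. By these scores none passed with the spread of the saline mice by limma (0 in each nicotine contrast, with 808, 1458, 762 and 1661 of 25802 genes on all chromosomes at an unadjusted p under 0.05). In C57BL/6J chronic nicotine mice the mean score was 1.49 for the iron exporter Slc40a1, 4.49 for Rpe65, -4.60 for Lcn2 and -1.65 for the complement gene C1qb. In DBA/2J chronic nicotine mice it was 4.28 for Tmem131l and -3.30 for Cpne9. In withdrawal it was 1.05 for the melanocortin receptor Mc3r in C57BL/6J and 2.46 for Rnf220 in DBA/2J. By S-score 11, 17, 11 and 6 lists passed camera in chronic C57BL/6J, chronic DBA/2J, withdrawal C57BL/6J and withdrawal DBA/2J, and with an estimated correlation 1, 0, 0 and 0.

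The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, averaged per array, stood at 11.4 in DBA/2J withdrawal saline mouse 5 and 11.02 in mouse 1, while the other 44 arrays ran from 10.3 to 10.8. The mean S-scores of the DBA/2J withdrawal nicotine mice, which use these saline mice as reference, were -4.93 for Kdm5d and -5.43 for Uty.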
